A study of Mus musculus with 12 samples.

How the data were processed

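Regulatory T cells were sorted by flow cytometry as CD4 and Foxp3 positive cells from C57BL/6 mice and lysed in TRIzol, and libraries were made from total RNA with SMARTer Stranded RNA-Seq kits (Takara), per the labels' protocols. The organ was not spelled out in the labels, though every sample title contains the letters Thy. The deposited values were raw read counts per gene symbol with no normalization, made with CASAVA, STAR 2.5.2b, STAR 2.3.0e and HTSeq 0.6.1p1 on build mm9, per the submitters' processing notes, which did not give the role of each STAR version, the annotation or the strand setting. The 5 summary entries of HTSeq were left out of library sizes and tests. Reads outside annotated features made up 44.3 to 46.9% of a library's reads, reads without a unique position 14.1 to 17.3%, unaligned reads 4.73 to 8.01%, ambiguous reads 0.584 to 0.678% and reads in genes 29.5 to 35.7%.

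Strand, chromosome, gene type, GC content and length were taken from GENCODE release M21 by gene symbol, which matched 54510 of 55453 genes. That release is on a later build than mm9, so no coordinates are given. Reads of protein-coding genes lay almost only in genes of the plus strand, 95.8 to 97.2% per library, and the notes gave no cause. The count table held 10875 protein-coding genes on the plus strand, of which 5629 had a mean count over 50, and 10907 on the minus strand, of which 924 did. Genes that overlap an exon of the other strand or share reads with a near-identical copy are uncertain.

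Comparisons used edgeR 4.0.16 in R 4.3.3. Genes with low counts were removed with filterByExpr on the 4 groups, which left 12411 of the 29806 genes with reads, libraries were scaled by TMM, and a quasi-likelihood model with 1 mean per group and robust estimation was fitted to all 12 libraries. Knockout was compared with floxed within males, within heterozygous females and over the mean of both contrasts, the difference between the female and the male contrast was tested, and floxed females were compared with floxed males. P-values were adjusted by Benjamini-Hochberg with a threshold of 0.05, and log2 fold changes are knockout over floxed. CPM are counts scaled to the TMM-adjusted library size.

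Lists of genes were fixed before the data were examined, 27 in all: Treg identity, genes low in Treg cells, IL-2 and STAT5 response, gamma chain receptors, T cell receptor response, NF-kB, immediate early and heat shock, immature double-positive thymocytes, thymocyte maturation, effector and recirculating Treg, S phase, G2 and M phase, interferon response, BCL2 family, Foxp3 locus, Foxp3 regulators, glycolysis, cholesterol synthesis, chemokine receptors and homing, ribosomal proteins, mitochondrially encoded, sex-linked, and markers of B, myeloid, thymic epithelial, erythroid and NK-like cells. Lists were tested by limma 3.58.1 camera on log2 CPM with a prior count of 2 and a preset correlation of 0.01, and again with an estimated correlation and with fry. Members were also adjusted over the list alone. The comparisons, tests and rule for naming genes were likewise set before the data were examined.

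The named genes were those with an adjusted p under 0.05, a mean log2 CPM of at least 1, no overlap between the genotypes within a sex and a symbol that is not a predicted model or receptor segment, taking the 12 largest rises and the 12 largest falls of a comparison. Where fewer than 6 qualified, the 6 genes with the smallest p were given as values. Foxp3, its neighbours, Il2ra, Ctla4 and Ikzf2 were always considered, as were up to 4 members of each list with a call or a called member.

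Alternatives fixed in advance were RLE normalization, DESeq2 1.42.0, limma-voom with quality weights, no low-count filter, a filter of at least 5 CPM in 3 libraries, the replicate number as a block, only the libraries of 1 sex, and each library left out in turn. Added after the data were seen were fits on plus-strand genes, on plus-strand genes without minus-strand exons, with a smooth trend on GC content and length removed per library (estimated on 5809 genes, with a value for 99.3% of tested genes), with the mean level of the myeloid list as a covariate, without female knockout libraries 1 and 3, and without male floxed library 4 and male knockout library 2. The splits of the libraries were refitted, 10 for 3 libraries against 3 and 100 within the sexes, the real one and 99 drawn with a fixed seed, out of 10 male by 20 female sets. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

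The pipeline was tested on simulated counts for 12411 genes. Without a GC trend, in the comparison over both sexes it recovered 5.97% of genes changed 1.5-fold, 37.3% of those changed 2-fold and 80.3% of those changed 4-fold, with 4 false calls among 86. In males these shares were 1.49, 19.4 and 59.1%, and in females 1.49, 11.9 and 54.5%. With a GC trend added to the simulated libraries, whose strength was set and not measured, the same fit recovered 0, 7.46 and 62.1% over both sexes, 0, 0 and 4.55% in males and 0, 0 and 16.7% in females. With the GC correction as well, the shares over both sexes were 8.96, 44.8 and 77.3%. The added trend was linear in the GC values that the correction used, so this recovery was favoured in advance. The simulated changes were alike in both sexes, so the power of the test of the difference between the sexes was not measured. Apart from the GC trend, simulated genes varied independently of each other. The false calls therefore do not measure those that differences shared by many genes between the real libraries can give.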

Results

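RNA was sequenced from regulatory T (Treg) cells, the CD4 T cells that carry the transcription factor Foxp3 and restrain immune responses, sorted by flow cytometry as CD4 and Foxp3 positive from C57BL/6 mice. CNS4 is a distal enhancer of the Foxp3 gene, and the series title concerns its part in the commitment of thymic Treg cells. The 12 libraries formed 4 groups of 3: males with the floxed, undeleted enhancer, males with the enhancer knocked out, and females labelled as heterozygotes of the floxed and of the knockout allele. Whether both alleles were in use in the sorted female cells was not given in the labels. Gene counts per library ran from 12423335 to 30244505 with a median of 14596845. The highest was male knockout library 3 and the next, male knockout library 1, had 16250798. The labels did not say whether each library came from a separate animal, so the p-values measure the spread between these samples. Replicates of a group differed beyond counting noise, with a chi-square per degree of freedom between 4.82 and 149.

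Genes annotated on the plus strand held 96.7% of the reads of protein-coding genes, against 3.34% for the minus strand. For example, Cd3d on the plus strand had 10488 to 23326 counts per library, while Cd3e on the minus strand had 263 to 600 and Cd4, by which the cells were sorted, 72 to 198. Most minus-strand genes therefore had low counts, though some named here did not, such as Gapdh on the minus strand at 298 to 610 CPM (counts scaled to library size). How far counts of minus-strand genes follow the level of their transcripts was not tested, and the strand is given with each of them. A low count of a minus-strand gene thus does not show a low transcript level. Xist on the minus strand had 0 to 18 counts per library, while Tsix on the plus strand, transcribed opposite to it, had 2 to 3109. Whether counts of such plus-strand genes hold reads of the gene opposite was not tested. A change counted under such a gene therefore need not be a change of its own transcript. Ikzf2, which encodes the Treg factor Helios, lies on the minus strand, and the counts of the Foxp3 neighbours Ppp1r3f and Ccdc22, both on the minus strand, did not exceed 2 in any library.

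Foxp3 on chromosome X was lower in each of the 3 knockout libraries than in each of the 3 floxed libraries of the same sex. In males it averaged 2496 ± 238 CPM, counts scaled to library size (SD, n = 3), in floxed and 1792 ± 297 CPM (SD, n = 3) in knockout cells, and in heterozygous females 2632 ± 43.8 CPM (SD, n = 3) and 1111 ± 621 CPM (SD, n = 3). Its log2 fold change was -0.48 (SE 0.30, adjusted p = 0.835) in males and -1.24 (SE 0.31, adjusted p = 0.103) in females by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Over both sexes it was -0.86 (SE 0.22, adjusted p = 0.0600 by the same edgeR test). Foxp3 did not pass the threshold in any of these comparisons. After a correction for GC content and transcript length the change over both sexes was -0.71 (SE 0.15, edgeR adjusted p = 0.0305, between 2.7e-04 and 0.212 over 23 alternatives). The sort on Foxp3 may limit how low its level could be, which was not tested, and counts of the gene do not show the enhancer itself. The female value moved to -1.79 (SE 0.16, edgeR adjusted p = 5.7e-04) without female knockout library 2, whose 1824 CPM lay above the 685 and 825 CPM of the other two, and to -0.53 (SE 0.16, edgeR adjusted p = 1, the highest over 17 alternatives) without libraries 1 and 3, where the lone sample left is assumed to vary like the other groups. Over both sexes it was -1.13 (SE 0.10, edgeR adjusted p = 0.00117) without female knockout library 2, and -0.50 without female knockout libraries 1 and 3. Foxp3 shares 856 exonic bases with genes on the other strand in GENCODE release M21.

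**Figure D1:**
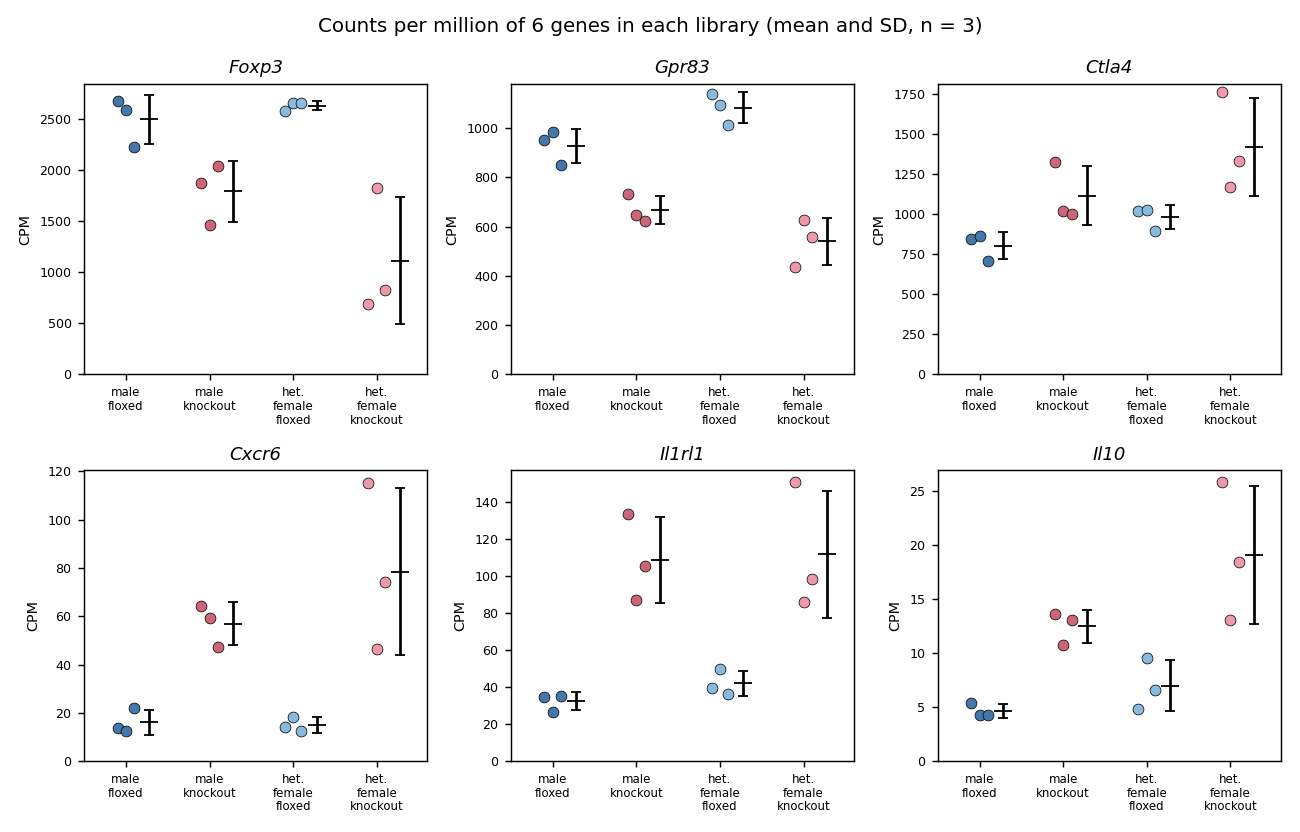
CPM, counts scaled to library size (vertical axes from 0), of 6 genes in each of the 12 libraries, by group; points are libraries and bars show the mean and SD of 3 libraries. Foxp3 and Gpr83 lay lower, and Ctla4, Cxcr6, Il1rl1 and Il10 higher, in every knockout library than in every floxed library of the same sex.

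The comparison of genotypes over both sexes asked which genes differed between knockout and floxed Treg cells whatever the sex. Cxcr6, a chemokine receptor, had the largest rise among the genes named by the rule, a log2 fold change of 2.11 (SE 0.24), from 16.0 ± 5.15 to 57.0 ± 8.72 CPM in males and from 14.9 ± 3.13 to 78.5 ± 34.7 CPM in females (SD, n = 3 each). Daw1 followed at 1.79 (SE 0.35) and Igsf9b at 1.69 (SE 0.22). Il1rl1, which encodes the IL-33 receptor, rose by 1.58 (SE 0.17), Il18rap, a subunit of the IL-18 receptor, by 1.52 (SE 0.18), the chemokine receptor gene Ccr2 by 1.43 (SE 0.23) and the cytokine gene Il10 by 1.44 (SE 0.21). Among the falls, Cybrd1, a ferric reductase gene, changed by -1.45 (SE 0.19), Samd3 by -1.35 (SE 0.15) and Gpr83, a receptor gene used as a Treg marker, by -0.74 (SE 0.09). In all, 411 of 12411 genes passed an adjusted p of 0.05 (edgeR, Benjamini-Hochberg), 332 higher and 79 lower in knockout. All 411 had the same sign in each sex, which a call on the mean of both contrasts favours, so it is no separate evidence. Plus-strand genes made up 379 of the calls and minus-strand genes 30. Of the 411, 265 had values that did not overlap between the genotypes within either sex and met the limits on level and symbol set for naming genes. Chance gives no overlap in 10% of genes within 1 sex and in 1% within both, and the 265 were counted only among called genes.

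The other large rises were those of Pla2g2d (1.54, SE 0.28), B3galt5 (1.48, SE 0.29), Dnah7a (1.42, SE 0.23, minus strand), Ptpn13 (1.39, SE 0.16) and Serpina3g (1.38, SE 0.16). The other large falls were those of Gimap1os (-1.43, SE 0.28, minus strand), Col11a2 (-1.40, SE 0.28), Mrpl23 (-1.35, SE 0.26), Tnnt2 (-1.21, SE 0.18), Kcnmb4os2 (-1.19, SE 0.18), Vmn2r97 (-1.07, SE 0.21), Pak6 (-1.06, SE 0.23), Gk5 (-1.01, SE 0.23), Ampd1 (-0.98, SE 0.18) and Mcf2l (-0.96, SE 0.21). Ctla4, an inhibitory receptor gene of Treg cells, rose by 0.50 (SE 0.12, edgeR adjusted p = 0.0457). Il2ra, which encodes the high-affinity chain of the IL-2 receptor, differed by 0.18 (SE 0.12, edgeR adjusted p = 0.395) and Ikzf2 on the minus strand by 0.17 (SE 0.19, edgeR adjusted p = 0.636). None of the 12 tested genes in and around the Foxp3 locus passed the threshold over all genes, and 1, Foxp3, was lower when adjusted over the list alone. The locus list had no call over all tested genes, but on plus-strand genes alone, 10 of the 12, it was lower by camera (median -0.51, adjusted p 0.0484, and 0.0427 in females). Without genes that share exonic bases with the minus strand, Foxp3 among them, the call was lost (gene list Foxp3 locus, adjusted p 0.424, and 0.431 in females). With an estimated correlation all 12 genes had an adjusted p = 0.427, and 0.455 in females.

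Effector and recirculating Treg genes moved together over both sexes. Of 27 tested members, 16 rose and none fell, against 18 that rose and 1 that fell adjusted over the list alone, with a median log2 fold change of 0.68. Besides Cxcr6, Il1rl1 and Il10, Icos, a costimulatory receptor gene, rose by 1.04 (SE 0.14). The list was higher by limma's camera with a preset correlation (adjusted p = 3.0e-13), and this call was lost at an adjusted p = 0.121 with an estimated correlation. Of 14 chemokine receptor and homing genes, 7 rose (8 adjusted over the list alone) and none fell, with a median of 0.50. They included Cxcr6, Ccr2 and Ccr6 (0.68, SE 0.11), and 5 of them are also in the effector list. Their camera adjusted p was 3.3e-04, and the adjusted p = 0.121 with an estimated correlation.

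Cell cycle genes rose as well. For the G2 and M phase, 8 of 23 members rose (18 adjusted over the list alone), none fell, and the median was 0.80. The mitotic motor gene Cenpe rose by 1.03 (SE 0.16), Tpx2 by 0.97 (SE 0.18) and Hmgb2 by 0.81 (SE 0.13). For the S phase, 8 of 20 rose (10 adjusted over the list alone), none fell, and the median was 0.54. Rrm1, a subunit of ribonucleotide reductase, rose by 0.77 (SE 0.10) and the replication helicase gene Mcm5 by 0.68 (SE 0.10). The camera adjusted p was 6.1e-12 and 2.8e-05, and with an estimated correlation the adjusted p = 0.217 and the adjusted p = 0.121. Glycolysis genes had 8 of 18 members higher (8 adjusted over the list alone), among them Eno1 (0.36, SE 0.08) and the minus-strand genes Gapdh (0.55, SE 0.10), Aldoa (0.41, SE 0.09) and Gpi1 (0.34, SE 0.07). Their median was 0.18 and the camera adjusted p 0.00899, with an adjusted p = 0.217 with an estimated correlation and a camera adjusted p of 0.151 over plus-strand genes alone. The median ran from 0.08 to 0.42 over 22 alternatives and was 0.42 after the correction for GC content. For these 5 lists the p with an estimated correlation was the highest over 22 alternatives, the lowest being 3.4e-16 for the effector list and 2.3e-04 for glycolysis.

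Treg identity genes went both ways, with 5 of 27 members higher and 1 lower (7 and 2 adjusted over the list alone). The integrin gene Itgae rose by 1.06 (SE 0.15), Cst7 by 1.04 (SE 0.18) and Capg by 0.80 (SE 0.12), and Gpr83 fell. The median was 0.17 and the camera adjusted p 0.0306, lost at an adjusted p = 0.427 with an estimated correlation, and without male knockout library 1 or female knockout library 2 (highest adjusted p 0.0729). Regulators and cofactors of Foxp3 had a median of -0.32 and a camera adjusted p of 0.0219 toward lower values, lost at an adjusted p = 0.582 with an estimated correlation and at a camera adjusted p of 0.206 after the correction for GC content (0.00840 to 0.867 over 22 alternatives). On plus-strand genes alone, 14 of the 29, the median was -0.14 and the camera adjusted p 0.626. The call was also lost without male floxed library 1, male knockout library 2 or female knockout library 3 (highest adjusted p 0.0845). The only member past the threshold rose: Rbpj, the nuclear effector of Notch signalling, at 0.70 (SE 0.13), beside 2 higher and 5 lower adjusted over the list alone. Genes past the threshold in lists with no call were Il10, Icos, Irf4 (0.57, SE 0.10), the minus-strand genes Hsp90aa1 (0.49, SE 0.10) and Hsp90ab1 (0.42, SE 0.10), Bik (0.89, SE 0.16), Gbp3 (0.59, SE 0.12) and Lef1 (-0.43, SE 0.10).

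Markers of myeloid and dendritic cells, which are not CD4 and Foxp3 positive T cells, had a median of 0.62 with none of 18 members past the threshold, alone or over all genes. The median ran from -0.19 without male knockout library 2 to 2.04 without male floxed library 4, the extremes over 22 alternatives. Their camera adjusted p was 0.0219, lost at an adjusted p = 0.748 with an estimated correlation, and without male floxed library 1 or 2 or male knockout library 2 (highest adjusted p 0.252). The summed level of Adgre1, Csf1r, Mrc1, Timd4 and Mpeg1, genes of macrophages chosen after the values were seen, ran from 85.3 to 1473 CPM. It was highest in female knockout library 3, at 1265 CPM in male knockout library 2, 1200 CPM in male floxed library 4 and 1047 CPM in female floxed library 1. The first principal component held 49.8% of the variance and set female knockout libraries 1 and 3 apart, at scores of 98.9 and 93.4, beside 13.0 for female knockout library 2. At the other end lay male knockout library 3 (-72.9) and male floxed libraries 2 (-68.8) and 1 (-45.7), away from male floxed library 4 (-25.8) and male knockout libraries 1 (-5.75) and 2 (0.177). Spearman's rho of a library's deviation from the gene means with GC content was -0.413, -0.147 and -0.316 in female knockout libraries 1 to 3. It was -0.0758, 0.0702 and 0.199 in female floxed libraries 1 to 3. Mitochondrially encoded genes held 4.04, 2.77 and 3.40% of gene counts in female knockout and 2.64, 2.37 and 2.27% in female floxed libraries. In females genotype thus cannot be told apart from these library traits, while in males the genotypes overlapped on them. Without female knockout libraries 1 and 3, which leaves 1 female knockout library, most of the 411 genes were no longer called over both sexes. With female knockout library 2 left out instead, 2940 were called, including all 411, and most were lower (1075 higher, 1865 lower). In limma-voom with quality weights, too, more genes were lower (2796) than higher (1834). The count fell to between 98 and 208 without floxed library 1 or 2 or knockout library 1 or 2 of the males, or any of the 3 floxed or knockout libraries 1 and 3 of the females, and rose to 785 without male knockout library 3.

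**Figure D2:**
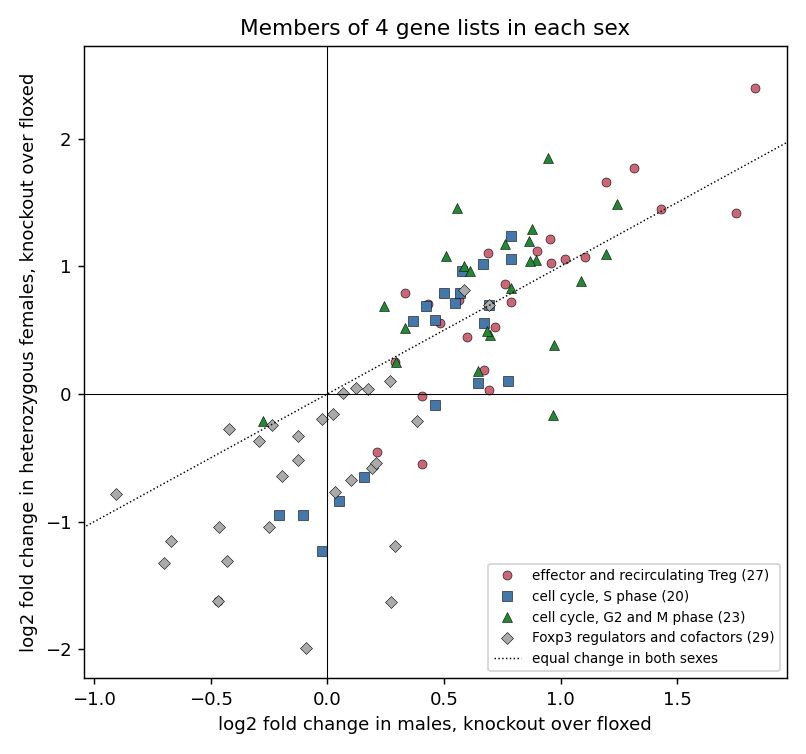
Log2 fold change (knockout over floxed) in males, horizontal axis, against that in heterozygous females, vertical axis, for each tested member of 4 gene lists; the dotted line marks an equal change. Most effector Treg and G2 and M phase genes lie above 0 in both sexes, with medians over both sexes of 0.68 and 0.80.

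In males alone, the comparison that carries a single X chromosome, 3 genes passed the threshold and all were higher in knockout cells. Fam129a, a stress-response gene, rose from 438 ± 54.0 to 799 ± 71.3 CPM (SD, n = 3), a log2 fold change of 0.87 (SE 0.11, edgeR adjusted p = 0.0432). Tmem154 rose from 178 ± 6.02 to 312 ± 13.3 CPM (SD, n = 3), by 0.81 (SE 0.10, edgeR adjusted p = 0.0432), and the third was the clone-based model 1810073O08Rik (1.58, SE 0.19), which lay outside the rule for naming genes and was named after its values were seen. Just above the threshold, at an edgeR adjusted p of 0.0585, lay Il1rl1 (1.75, SE 0.25), Ptpn13 (1.46, SE 0.22), Abcb1a (1.14, SE 0.17) and Samd3 (-1.54, SE 0.22). Of the 27 effector and recirculating Treg genes none passed over all genes and 17 were higher adjusted over the list alone, with a median of 0.69 and a camera adjusted p of 3.5e-17. With an estimated correlation this was an adjusted p = 0.0626. Markers of other cells leaned up in males as well, without a call: myeloid and dendritic genes had a median of 0.27 with 17 of 18 above 0, thymic epithelium 0.72 with 6 of 6 and B cells 0.31 with 5 of 5 (camera adjusted p 0.111, 0.473 and 0.473). After the correction for GC content myeloid genes were called higher in males (camera adjusted p 0.0226). With an estimated correlation and no GC correction their camera adjusted p was 0.882.

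The G2 and M phase genes had a male median of 0.76 (9 higher adjusted over the list alone, camera adjusted p = 2.5e-12, and adjusted p = 0.153 with an estimated correlation). The S phase genes had a median of 0.52 (9 higher adjusted over the list alone, camera adjusted p = 1.6e-07, and adjusted p = 0.0626 with an estimated correlation). Chemokine receptor, glycolysis, Treg identity, BCL2 family and immediate early and heat shock genes were also higher by camera, at adjusted p values between 1.7e-04 and 0.0376, and 0 of the 8 lists held with an estimated correlation. The call of immediate early and heat shock genes was lost without floxed library 4 or knockout library 1 or 3 (highest adjusted p 0.390), and that of BCL2 family genes without floxed library 1 or 4 or knockout library 3 (highest adjusted p 0.229). The immediate early and heat shock call was also lost on plus-strand genes alone (camera adjusted p 0.465) and after the GC correction (0.0583). It held in 5 of 15 alternatives. The 3 gene calls were lost when any male library other than floxed 4 was left out (0 genes each) and after the correction for GC content and length (0 genes), and without floxed 4 there were 35. DESeq2 called 235 genes in males and limma-voom with quality weights 177, beside 1008 genes at an unadjusted p under 0.05 in edgeR.

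In heterozygous females, 25 genes passed the threshold, 23 higher and 2 lower in knockout cells. The largest rises were those of Cxcr6 (2.39, SE 0.35), the microtubule gene Map2 (1.89, SE 0.23), Il18rap (1.64, SE 0.25), the growth factor gene Hgf (1.56, SE 0.21), the lectin receptor gene Klrb1f (1.53, SE 0.25), Cep112 (1.28, SE 0.19) and Il18r1, the other IL-18 receptor subunit (1.25, SE 0.19). Replication genes were among them: Orc1, a subunit of the origin recognition complex, rose by 1.11 (SE 0.17), Pole, the catalytic subunit of a replicative polymerase, by 1.02 (SE 0.14) and Rrm1 by 0.96 (SE 0.15). Zcchc18 (1.13, SE 0.15), Sdcbp2 (1.11, SE 0.17) and She (1.07, SE 0.17) also rose. Gpr83 fell from 1082 ± 62.9 to 539 ± 96.0 CPM (SD, n = 3), with an edgeR adjusted p of 0.0265, and Kcnmb4os2 changed by -1.62 (SE 0.26). The edgeR adjusted p of the 25 genes was 0.0265 at the lowest, and all 25 were also called over both sexes. That comparison includes the same female libraries, so this is no separate evidence.

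Effector and recirculating Treg genes had a female median of 0.79, with 1 of 27 members past the threshold and 17 higher and 1 lower adjusted over the list alone (camera adjusted p = 1.4e-08, and adjusted p = 0.392 with an estimated correlation). The G2 and M phase genes had a median of 0.96, with none past the threshold and 13 higher adjusted over the list alone (camera adjusted p = 1.8e-08, and adjusted p = 0.455 with an estimated correlation). Immature thymocyte genes had a median of 0.55, with 11 of 12 above 0 and no call (camera adjusted p 0.0613). On plus-strand genes alone they were called higher (camera adjusted p 0.0489). With an estimated correlation over all genes their camera adjusted p was 0.682. Chemokine receptor, S phase, mitochondrially encoded and myeloid genes were higher and Foxp3 regulators lower by camera, at adjusted p values from 0.00154 to 0.0456. Myeloid genes had a median of 0.98, above that of the effector list, with 16 of 18 members above 0, mitochondrially encoded genes 0.43 with 12 of 12, and Foxp3 regulators -0.54 (on plus-strand genes alone -0.22, camera adjusted p 0.322). Of these lists, 0 of the 7 held with an estimated correlation. After the correction for GC content the camera adjusted p was 0.0681 for Foxp3 regulators and 0.651 for mitochondrially encoded genes. The call of myeloid genes was lost without floxed library 2 or 3 or knockout library 2 or 3 (highest adjusted p 0.108), and that of S phase genes without knockout library 2 (adjusted p 0.0816). No gene passed when any single female library other than knockout 2 was left out, or after the correction for GC content and length (0 genes each, against 3089 without knockout 2, 935 higher and 2154 lower). DESeq2 called 706 genes and limma-voom with quality weights 5437, of which 2289 were higher and 3148 lower, beside 2378 at an unadjusted p under 0.05 in edgeR.

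**Figure D3:**
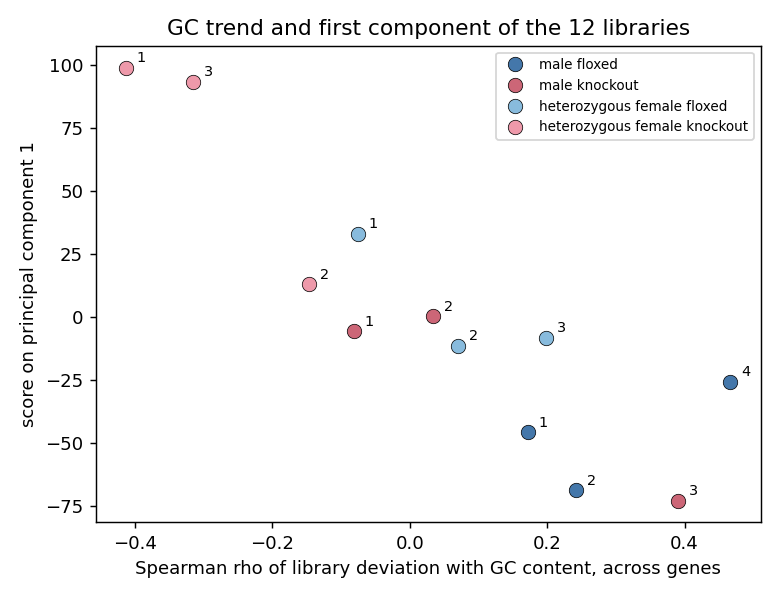
Score of each library on the first principal component of log2 CPM (vertical axis) against Spearman's rho, across genes, between the library's deviation from the gene means and GC content (horizontal axis); numbers are replicates. Female knockout libraries 1 and 3 lie at 98.9 and 93.4, with rho of -0.413 and -0.316. Female knockout library 2 had a rho of -0.147, and the female floxed libraries had -0.0758, 0.0702 and 0.199.

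Tmem154 was the only gene called in both sexes, and it was higher in both, where independent lists would share 0.00556 genes higher in both (two-sided Fisher's exact test on the lists of 3 and 25 genes, p = 0.00603). At an unadjusted p under 0.05, 491 genes were shared and 485 had the same direction: 380 were higher in both, against 64.3 for independent lists, and 105 lower in both, against 33.0. The male and female log2 fold changes, which share no library, had a Pearson r of 0.44 and a Spearman rho of 0.48 across 12411 genes, which are not independent replicates. Both sexes were fitted with 1 shared estimate of spread per gene, so the lists above are not independent either. The GC trend between libraries was not removed for the overlap or for these correlations. No gene passed the test of the difference between the female and the male change (0 of 12411 in edgeR and 0 in DESeq2, 1040 in limma-voom, 339 at an unadjusted edgeR p under 0.05). The difference for Foxp3 was -0.77 (SE 0.43, edgeR adjusted p = 0.892). Without female knockout library 2 the edgeR count was 1108 (17 higher, 1091 lower), and the difference for Foxp3 was -1.33 (SE 0.20, edgeR adjusted p = 0.00629). Without female knockout libraries 1 and 3, which leaves 1 female knockout library, the difference for Foxp3 was -0.04.

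Floxed females and floxed males, compared to check the labelled sex, differed in 4 genes (edgeR, 762 at an unadjusted p under 0.05), all of them sex-linked; 20 genes passed without female floxed library 2. Tsix, which is transcribed opposite to Xist, was at 151 ± 15.3 CPM in floxed females and 0.239 ± 0.103 CPM in floxed males (SD, n = 3). Xist, on the minus strand, had 9 to 18 counts in the female libraries and 0 in the male ones. Which of the 2 transcripts gave the reads counted under Tsix was not tested, so Tsix serves here only as a check of sex. The Y-linked genes Eif2s3y (330 ± 59.5 CPM) and Kdm5d (218 ± 27.5 CPM) were present in floxed males and near 0 in females (0.176 and 0.154 CPM). Uty, Y-linked and on the minus strand, was at 3.27 ± 0.846 CPM in floxed males and had no counts in any female library. Tsix counts of all 6 females, 2012 to 3109, stood apart from the 2 to 10 of all 6 males, so no library went against its labelled sex, although Tsix shares 1980 exonic bases with the other strand.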

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

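The GC correction, the myeloid covariate, the leave-out of female knockout libraries 1 and 3, the comparison with immature thymocytes in each sex and the GC-corrected splits were tests chosen only after the data were seen. A test of the difference between the female and the male change singled out 5 lists by camera with a preset correlation. Interferon response genes had a median difference of 0.30 (adjusted p = 0.00493), immature double-positive thymocyte genes 0.42 (adjusted p = 0.0262) and mitochondrially encoded genes 0.23 (adjusted p = 0.0216). IL-2 and STAT5 response genes had -0.49 (adjusted p = 0.0262) and Foxp3 regulators and cofactors -0.45 (adjusted p = 0.00493). With an estimated correlation each of the 5 had an adjusted p = 0.844, after the GC correction the adjusted p values lay between 0.0729 and 0.734, and without female knockout libraries 1 and 3 each was 0.848. The number of lists fell to 1 without male knockout library 3, 2 without male floxed library 4 or female knockout library 3, and 3 without male knockout library 1.

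The first pattern was the lower Foxp3 and the genes called by genotype over both sexes, set against GC-linked bias and the grouping of the libraries. After the GC correction Foxp3 was at -0.71 (SE 0.15, from -0.86). Of the 411 calls, 61.6%, 253 genes, were called in the same direction. These values argue against the smooth trend that was removed as the whole cause. In males alone and in females alone, though, 0 genes were called after the correction. GC-linked bias beyond that trend stays open. The splits within the sexes were the real one and others drawn at random from all 10 male by 20 female sets. For 3 of 100, the real one included, the count was as high as 411 (highest other 2083). After the GC correction 3 of 100 were as high as 316 (highest other 2593). The other high splits exceeded the real count. The share therefore cannot exclude a chance alignment of genotype with other differences between the libraries. Both other high splits set male floxed libraries 1 and 2 and knockout 3 against the other males, 1 of them with the true female split (1197, and 1686 after the GC correction), while the same male set gave 0 genes in 10 of its 12 splits that were drawn, out of 20. The highest split, with 2593 genes after the GC correction, also set female floxed libraries 2 and 3 and knockout 2 against the other females. In each sex its set held the 3 lowest scores on the first principal component. They ran from -72.9 to -45.7 in males and -11.4 to 13.0 in females, with the rest at -25.8 or above and 33.1 or above. This points to a structure of the samples, in part along that component, that the GC correction did not remove. The male set alone does not account for it, and genotype and this structure both stay open.

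The second pattern was the higher level of effector and recirculating Treg genes, set against myeloid RNA in the sorted cells. With the myeloid score as a covariate the median kept 88.9% of its value (95% bootstrap interval 74.6 to 104), at 0.61 from 0.68. That argues against myeloid RNA as the whole source, and how large a contribution it made stays open. The genotype is a candidate explanation that the design names. Counts over all sorted cells cannot tell a change within cells from a change in the mix of Treg cells, and this was not tested.

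The third pattern was the higher level of G2 and M phase genes, set against immature thymocytes, which the sort on Foxp3 should remove. In males the median of the immature thymocyte list was -0.02 and that of the cell cycle list 0.76, a difference of -0.78 (SE 0.16). This SE and the female one below come from resampling the members of the lists. They do not measure the spread between libraries. In these male libraries the thymocyte genes did not rise with the cycle genes. In females the medians were 0.55, with 11 of 12 thymocyte genes above 0, and 0.96, a difference of -0.42 (SE 0.21), within 2 SE, so there immature thymocytes stay open. A greater share of dividing Treg cells in the knockout may account for the pattern, as a hypothesis not tested here.

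In males 2 of 10 splits of the 6 libraries, the real one included, gave as many genes as the real 3, and the highest other, floxed 1 and 2 with knockout 3 against the rest, gave 432. In females 1 of 10 splits did, with 25 genes against 0 in the highest other, and for floxed females against floxed males 1 of 10, with 4 against 0. With 10 splits no share under 0.05 can be had. For the difference between the sexes the real count was 0, which 100 of 100 splits reach whatever the data, so the splits say nothing there (edgeR, 339 at an unadjusted p under 0.05, 0 in DESeq2 and 1040 in limma-voom), the highest other being 1197.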

How the results depend on the processing

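The fits on plus-strand genes, with the GC correction or the myeloid covariate, and those leaving out 2 libraries together were tests chosen only after the data were seen. The cause of the shifts below was not tested. In males 3 genes became 235 in DESeq2, 177 in limma-voom and 26 with no filter. They became 0 with the replicate block, with the male libraries alone, on plus-strand genes, with the GC correction, with the myeloid covariate and without male floxed 4 and knockout 2. Leaving out 1 library gave 0 to 35, 35 without floxed 4 and 0 without any other. In females 25 became 706 in DESeq2, 5437 in limma-voom, 94 with no filter, 50 with the stricter filter, 16 without minus-strand exons, and 13 with the myeloid covariate. They became 0 with the replicate block, the female libraries alone, the GC correction and without knockout 1 and 3. Leaving out 1 library gave 0 to 3089, 3089 without knockout 2 and 0 without any other. Over both sexes 411 became 1129 in DESeq2, 4630 in limma-voom, 1218 with the replicate block (499 higher, 719 lower) and 44 without female knockout 1 and 3. Leaving out 1 library gave 98 to 2940. The counts were 140 and 188 without male floxed 1 and 2, and 153, 208 and 785 without male knockout 1, 2 and 3. They were 196, 103 and 98 without female floxed 1, 2 and 3, and 192, 2940 and 163 without female knockout 1, 2 and 3. The difference between the sexes gave 1040 in limma-voom and 0 to 1108 leaving out 1 library, 1108 without female knockout 2. Floxed females against males gave 59 in DESeq2, 9 in limma-voom, 12 with no filter, 2 without minus-strand exons, and 7 with the GC correction. Leaving out 1 library gave 3 to 20, 20 without female floxed 2. Foxp3 in females was -1.25 in DESeq2 (adjusted p 0.00708) and -1.65 in limma-voom (adjusted p 3.7e-04), with -1.79 to -1.004 leaving out 1 library; in males it was -0.57 to -0.34. The overlap of 1 gene became 485 at an unadjusted p, 141 in limma-voom and 2 with the stricter filter. Lists with an estimated correlation were 0 in males, females, both and for the difference, and with fry 5, 3 and 0 in males, females and for the difference. Lists in females were 4 without minus-strand exons. Lists for the difference were 3 with the replicate block, 3 on plus-strand genes, 0 without minus-strand exons, 0 with the GC correction and 1 without female knockout 1 and 3. Leaving out 1 library gave 7 to 9 lists in males, 6 to 10 in females, 6 to 10 over both and 1 to 6 for the difference.

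Camera's direction turned, with a call before or after, for the lists that follow, given with their medians. In females it turned for mitochondrially encoded genes with the GC correction (0.0020, still above 0, adjusted p 0.651). Over both sexes it turned for the interferon response without female knockout 1 and 3 (-0.13, called lower at 0.0283). For the difference between the sexes it turned without female knockout 1 and 3 for immature thymocytes (-0.11) and interferon response (0.0035, still above 0), both at 0.848, and ribosomal proteins (-0.12, called lower at 0.0281). Ribosomal proteins were also called lower without female knockout 1 (-0.17, adjusted p 0.00381), with -0.17 to 0.11 leaving out 1 library. With the replicate block G2 and M phase (-0.29) and myeloid genes (-1.66) were called lower, each at 0.0389. None of these calls toward lower values was made in the unaltered test. The IL-2 and STAT5 median for the difference changed sign without female knockout 1 and 3 (0.02 from -0.49) while camera's direction stayed. Same-numbered libraries did not all deviate together (r = 0.44 and -0.61 in males, 0.19, 0.28 and -0.22 in females, across genes), nor did each correlate best with its own number. These values do not show that the numbers pair the samples. As deviations from means of 3 libraries, they cannot exclude it either. Named genes were counted once for each comparison that named them, 203 in all. Lists were counted once for each comparison tested, 108 in all. Under RLE normalization 201 of the 203 and 108 of the 108 kept their direction and side of the threshold. DESeq2 moved 53 of the 203 past the threshold, and the GC correction took 28 of the 203 below it. In the simulated counts, genes changed 1.5-fold were mostly not recovered.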

Other observations

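The immature thymocyte comparison among the tests was chosen only after the result was seen. Genes low in Treg cells had 1 of 17 members lower over both sexes, Lef1, with a median of -0.18 (camera adjusted p 0.387; 1 higher and 2 lower adjusted over the list alone). Of the IL-2 and STAT5 response only Il10 passed (19 members, median -0.16, camera adjusted p 0.619; 1 higher adjusted over the list alone). The gamma chain receptors and their kinases had a median of -0.22 with none of 13 past the threshold, alone or over all genes (camera adjusted p 0.229). Of 19 T cell receptor response genes 2 rose, Irf4 and Icos, with a median of -0.21 (camera adjusted p 0.879; 2 higher and 1 lower adjusted over the list alone). NF-kB genes had a median of -0.02 (camera adjusted p 0.879; 1 higher and 1 lower adjusted over the list alone). Of 12 immediate early and heat shock genes 2 rose, the minus-strand chaperone genes Hsp90aa1 (0.49) and Hsp90ab1 (0.42), with a median of 0.18 (camera adjusted p 0.161; 2 adjusted over the list alone).

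Over both sexes immature thymocyte genes had a median of 0.33 (camera adjusted p 0.229; 2 higher adjusted over the list alone) and thymocyte maturation genes -0.0093 (0.879; none adjusted over the list alone). Interferon response genes had 0.04 (0.879; 1 of 21, Gbp3, higher, also adjusted over the list alone), and BCL2 family genes 0.44 (0.0784; 1 of 12, Bik, higher, and 2 higher and 1 lower adjusted over the list alone). The Foxp3 locus had -0.47 (0.0872, and 0.427 with an estimated correlation; 0.0484 on plus-strand genes alone, and 0.424 without those sharing exonic bases with the minus strand), cholesterol synthesis genes 0.19 (0.0872), ribosomal proteins 0.08 (0.140), mitochondrially encoded genes 0.26 (0.0784) and sex-linked genes 0.18 (0.201). Markers of B cells had 0.54 (0.211), thymic epithelium 0.50 (0.619), erythroid cells 0.09 (0.925) and NK-like cells 0.45 (0.528), with no member past the threshold over all genes. Adjusted over the list alone, 1 was lower in the Foxp3 locus and 1 was higher and 1 lower among NK-like markers. The p in parentheses are camera adjusted p values.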
